A study of Solanum tuberosum with 72 samples.

How the data were processed

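RNA of potato (Solanum tuberosum) seedlings was measured on 72 two-colour cDNA microarrays, which carry spotted cDNA clones and compare 2 dye-labelled RNA samples on 1 slide. Per the labels, the Cy3 dye marked a stressed or unstressed sample and the Cy5 dye a pooled control reference of the same tissue, time and replicate number, so each of 18 reference pools was used on 4 arrays. The authors deposited 1 value per spot and array for 32448 spots. Per the labels' processing notes, the submitters named limma, with no version, and no background correction, normalization or filter is given in the labels. The values were read as log2 ratios deposited by the authors, since they stepped at log2 of ratios rounded to 2 decimals. Array medians lay between 0 and 0.014, so that the centring was taken as done by the authors, and scaling between arrays remained unknown. Scanner files were not used here.

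Which dye stood in the numerator was not stated. The rule set before the data were examined relied on small heat shock proteins, and 0 of the named genes belonged to that list. A basis chosen after seeing the data was used in its place. In 192 cases a probe had values on all 3 stressed arrays and on none of the 3 unstressed arrays of a tissue and time. The cases were added over tissues, stresses and times, so 1 probe can count in several. Of these cases, 44 had a mean beyond 1 in size, and all 44 were above 0. This is the sign that a transcript present in the stressed sample and weak in the reference gives. The deposited sign was therefore kept as stressed over reference, and all directions are likely directions on this basis. With the sign turned, higher and lower exchange throughout. All arrays had the same dye orientation. Of 2556 pairs of arrays, 1 correlated below -0.3 over probes, namely leaf cold at 27 h replicate 3 with leaf heat at 9 h replicate 2 (r = -0.334). The dyes are stated and cold and heat could oppose each other, so the direction was kept for these as well. The highest correlation was 0.906, between root cold at 27 h replicates 1 and 2.

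Most clones were spotted in duplicate. The layout was found from the annotation, in which all 905 annotated clones had 2 spots at the same repeating offsets, and was applied to the unannotated spots. The duplicate spots of annotated clones correlated with a median of 0.932 across arrays, those of unannotated pairs with 0.818, and spots paired at random with 0.002. The 2 spots of a pair were averaged into 15360 probes, of which 11037 had a value on at least 1 array. A further 1728 spots outside the layout held no value on any array. The number of spots with a value ranged from 15580 to 20545 per array. Platform annotation gave 1 gene symbol for 815 probes, several for 90 and none for 14455, and only the first kind was named. Of these, 363 probes of 197 genes had a name other than a locus number. All 430 gene identifiers were found in the gene table. The number of arrays limits the precision of all values.

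A probe was tested in a tissue when at least 2 of the 3 arrays of every group of that tissue held a value, which left 8726 probes in leaf and 8209 in root. Group means of the 12 groups of a tissue were computed in R 4.3.3 with 1 shared variance per probe over 36 arrays, moderated by limma 3.58.1. For each stress, the differences between stressed and unstressed samples at 3, 9 and 27 h were tested together with limma's moderated F-test, and p-values were adjusted over probes after Benjamini and Hochberg with a threshold of 0.05. The direction of a probe was the sign of its mean change over the 3 times. Differences between times were tested with an F-test over 2 contrasts, and differences between tissues in a fit of all 72 arrays. Array preparation used Python 3.11.15 with NumPy 2.4.6 and pandas 2.3.3, and plots used matplotlib 3.10.9. The fit was checked against limma's own on the probes with a value on every array of a tissue. The code for a block and for array weights was checked against limma on simulated data. In a simulation with the real missing values and spreads, cold changes of 1 on the log2 scale were found for 49 of 50 leaf probes and 46 of 50 root probes. Changes of 0.5 were found for 35 and 29 of 50.

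Named genes were chosen by a rule set before the data were examined. It took, per stress, tissue and time, the 4 largest rises and 4 largest falls among named probes past the threshold whose 3 stressed arrays all lay on 1 side of the unstressed arrays. It added the 3 members of each gene list with the smallest adjusted p in any comparison and the 2 with the smallest in each comparison. For differences between tissues and times, it took the 6 named probes with the smallest adjusted p. Where probes of a gene disagreed, this is stated.

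Of the 28 gene lists set before the data were examined, 22 matched no gene name, because the annotation gives short symbols, and 2 had 3 or more probes in root. The photosynthetic light reactions, which also serve as leaf markers, kept the members set beforehand (cab1, PSBO, psbP and PSBR). In leaf only 5 probes of 2 of these genes, psbP and PSBR, were tested, against 11 probes of all 4 genes in root. The other 20 of 21 lists were grouped by known function after the annotation was read and before any expression statistic was computed, and 17 had at least 3 probes in each tissue. Lists were tested with camera on the moderated t statistics of the mean change, with a preset inter-gene correlation of 0.01, and again with a correlation estimated per list. The 102 list tests were adjusted together. With the preset correlation 20 passed the threshold, and with the estimated correlation 0 did, at a smallest adjusted p of 0.12.

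Replicate numbers pair the samples, because the labels give 1 independent experiment per number and 1 reference pool per tissue, time and number. Deviations from the group means of arrays sharing a pool correlated with a mean of 0.199 in leaf and 0.202 in root. For arrays of the same number at other times the mean was 0.066 and 0.043. For arrays of the same time with other numbers it was -0.10 and -0.101. The last values follow from the first, since the deviations of a group sum to 0, and are no further sign of pairing. The fit without a block was chosen beforehand, and the fit with the pool as a block was an alternative. The other alternatives were median centring, scale normalization, 2 other filters on missing values, robust moderation, array weights, a fit of the 18 arrays of 1 stress and its unstressed samples, the stressed ratios without the unstressed arrays, and leaving out each replicate. A filter on the correlation of the 2 spots of a probe at 0.5 was added after seeing the data.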

Results

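The study followed how potato seedlings respond to cold, heat and salt. Plants of the variety Gilroy were grown from true seed on rafts in hydroponic boxes for 5 weeks at 25 °C with 16 h of light and 8 h of dark. The medium was then replaced by medium chilled to 4 °C, warmed to 35 °C or supplemented with NaCl, at 100 mM in the sample description and 150 mM in the treatment label, or by plain medium for the unstressed samples. Leaf samples, which were the aerial parts, and root samples were taken after 3, 9 and 27 h. Each sample pooled 6 plants of 2 boxes, and each reference pool came from 6 boxes. The 24 groups of tissue, condition and time held 3 samples each, from 3 independent experiments. Between 15580 and 20545 of the spots of an array had a value. Mean correlations between the replicates of a group ran from 0.282 in heat-stressed leaves at 27 h to 0.864 in cold-stressed roots at 9 h. Changes are log2 differences between stressed and unstressed samples. Without a stated time they are means over the 3 times ± SE from up to 9 stressed and 9 unstressed arrays, and at a stated time they rest on 2 or 3 arrays of each. The sign of the deposited ratios is a likely one, and adjusted p-values come from limma.

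In cold-stressed leaves, RSI5 rose by 2.96 ± 0.18 (adjusted p = 1.8e-11) and was up at all 3 times. The chitinase ChtA1 rose by 2.78 ± 0.27 and 2.68 ± 0.30 on its 2 probes, and the first of these climbed from 1.05 ± 0.47 at 3 h to 4.52 ± 0.47 at 27 h. STUGE45, a UDP-glucose 4-epimerase that supplies sugars to the cell wall, rose by 2.40 ± 0.17 (adjusted p = 6.1e-11), and the lignin pathway enzyme CCoAOMT by 1.92 ± 0.17. At 3 h the wound-induced protein kinase StWIPK stood at 2.40 ± 0.30 and the factor STWRKY8 at 2.17 ± 0.40. The photosystem II protein psbP fell by 1.12 ± 0.13 (adjusted p = 6.3e-07), and the chloroplast triose phosphate translocator TPT fell by 0.93 ± 0.12 on 1 of its 2 probes. LOX-H1, a chloroplast lipoxygenase of oxylipin synthesis, fell by 1.58 ± 0.32, and all 4 of its probes passed the test in that direction.

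Among the gene lists in cold leaves, all 6 probes of the 4 cell wall and nucleotide sugar genes rose (adjusted p = 0.00094), including RGP2 by 1.11 ± 0.13. Of 24 probes for the methionine cycle and polyamines, 16 rose and 0 fell (adjusted p = 0.00094), among them the S-adenosylmethionine synthetase METK2 by 1.01 ± 0.12. Of 13 protein kinase and phosphatase probes, 9 rose and 1 fell (adjusted p = 0.0099), with StMKP1 up by 1.11 ± 0.14. Transcription factors had 6 of 17 probes that rose and 0 that fell (adjusted p = 0.049). Of 7 probes for carbon fixation and photorespiration, 6 fell and 0 rose (adjusted p = 0.005), with transketolase (TK) down by 0.83 ± 0.12 (the change was -0.83). With an estimated correlation the adjusted p of these lists was 0.15, 0.43, 0.42, 0.15 and 0.43 in the same order. Starch genes split, as the amylase AMYA1 rose by 1.36 ± 0.16 and the branching enzyme SBE1 by 0.91 ± 0.10, while granule-bound starch synthase (GBSS) fell by 0.63 ± 0.19. The list had 7 probes that rose and 8 that fell of 23 (adjusted p = 0.73). Photosynthesis probes fell in 3 cases and rose in 1 of 5, and 5 of 5 passed when adjusted over the list alone. They belonged to psbP and PSBR, as cab1 and PSBO were not tested in leaf. The 1 rising probe belonged to PSBR, at 1.85 ± 0.18, while a second PSBR probe fell, so the probes of this gene disagreed.

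In all, cold changed 3425 of 8726 leaf probes, 1804 up and 1621 down, and 105 of 178 named genes. At 3, 9 and 27 h alone 1559, 2109 and 2087 probes passed. Without replicate 2 the count was 1764.

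**Figure D1:**
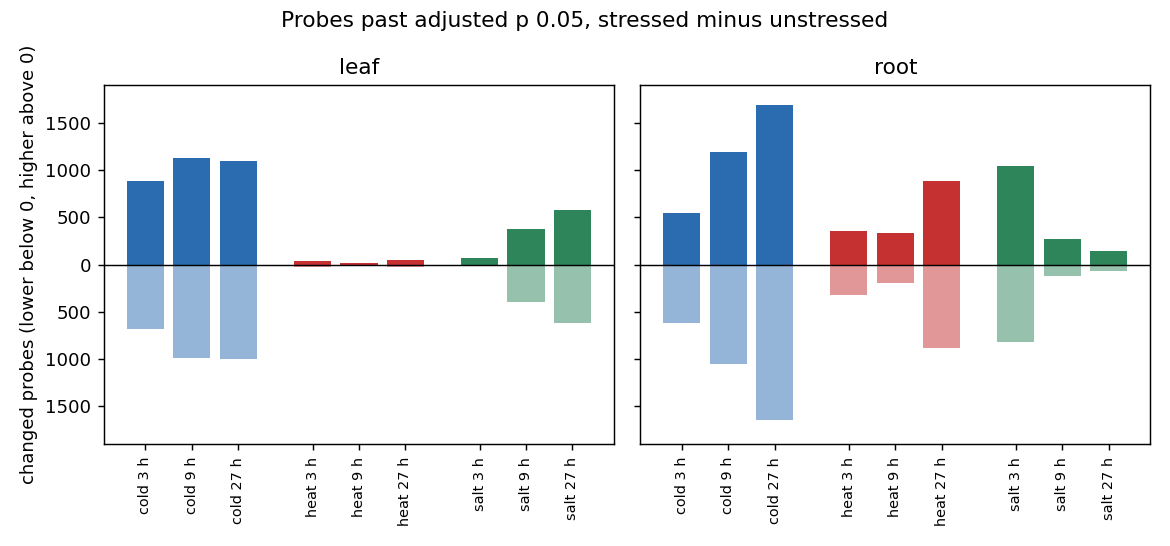
Probes past the adjusted threshold at each time, with the number higher in stressed samples above 0 and the number lower below 0, for leaf and root. Cold called the most probes in roots at 27 h (3335), heat the fewest in leaves at 9 h (22), and salt went from 76 to 1190 in leaves and from 1864 to 215 in roots between 3 and 27 h.

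In heat-stressed leaves, the late embryogenesis abundant protein Lea fell by 1.02 ± 0.14 (adjusted p = 0.00018) and agpS3, a subunit of the starch-building ADP-glucose pyrophosphorylase, fell by 0.77 ± 0.10 (the change was -0.77, adjusted p = 0.00028). A cyclophilin, cyp, fell by 0.50 ± 0.10 on 1 of 4 probes, and glyceraldehyde-3-phosphate dehydrogenase (GAPDH) fell by 0.36 ± 0.07 on 1 of 8. SI1 rose by 0.46 ± 0.08 on the probe named by the rule, and all 3 of its probes rose. The S-adenosylmethionine synthetase METK1 rose by 0.45 ± 0.09 on 1 of 7 probes, and sterol side chain reductase StSSR1 by 0.49 ± 0.10 (adjusted p = 0.021). The 7 carbon fixation probes shifted down as a list (adjusted p = 0.015, and 0.5 with an estimated correlation) with 0 members past limma's own test, and 2 at unadjusted p below 0.05. In the other lists at most 1 probe passed, and the 14 co-chaperone and cyclophilin probes included 1 that fell. Of the 5 photosynthesis probes, all of psbP and PSBR, 0 passed limma's test, 0 when adjusted over the list alone and 0 at unadjusted p below 0.05.

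Heat changed 285 of 8726 leaf probes, 164 up and 121 down, and 8 of 178 named genes. At unadjusted p below 0.05 there were 1349. At 3, 9 and 27 h alone 66, 22 and 74 probes passed. With the reference pool as a block the count was 482, with scale normalization 1001, with array weights 819 and against the reference without the unstressed arrays 1299. Without replicate 1, 2 or 3 it was 59, 63 or 31.

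In salt-stressed leaves, ChtA1 rose by 2.49 ± 0.27 and 2.53 ± 0.30 on its 2 probes, RSI5 by 1.97 ± 0.18 (adjusted p = 5.7e-08) and STUGE45 by 1.63 ± 0.17. Hydroperoxide lyase (HPL), which makes leaf aldehydes from fatty acid hydroperoxides, stood at 0.00 ± 0.34 at 3 h and rose by 2.02 ± 0.34 at 27 h. The apoplastic invertase InvCD141 fell by 1.14 ± 0.19, with -0.19 ± 0.33 at 3 h and -1.74 ± 0.33 at 27 h. Neither passed the test of a difference between times (adjusted p = 0.13 and 0.3). GDCST, the T protein of glycine decarboxylase in photorespiration, fell by 0.76 ± 0.13, proteinase inhibitor PIN-II fell by 0.81 ± 0.15 on 1 of 4 probes, and cy-F1 fell by 0.68 ± 0.17.

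The lists in salt leaves moved as follows. Carbon fixation and photorespiration had 3 of 7 probes that fell and 0 that rose (adjusted p = 0.0099). Lipoamide dehydrogenase LPD2 of the respiration list fell by 0.68 ± 0.13 (the change was -0.68), and in that list 2 of 24 probes rose and 1 fell. Cell wall genes had 2 of 6 probes that rose (adjusted p = 0.018), and pathogenesis-related proteins had 2 of 4, both ChtA1 (adjusted p = 0.005). Co-chaperones and cyclophilins had 4 of 14, all of 1 gene (adjusted p = 0.021). The methionine cycle had 4 of 24, which belonged to 2 genes (adjusted p = 0.03). With an estimated correlation the adjusted p of these 5 lists, respiration left aside, was 0.43, 0.43, 0.42, 0.52 and 0.6. Among starch and sucrose genes, 6 probes rose and 2 fell of 23 (adjusted p = 0.15), with SBE1 up by 0.93 ± 0.10 and sucrose synthase sus4 by 0.87 ± 0.10. Both auxin response repressors fell, IAA3 by 0.53 ± 0.10 (the change was -0.53) and IAA2 by 0.51 ± 0.11. Of 5 photosynthesis probes, all of psbP and PSBR, 1 rose and 1 fell, and 3 of 5 passed when adjusted over the list alone.

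Salt changed 1475 of 8726 leaf probes, 703 up and 772 down, and 47 of 178 named genes. At 3, 9 and 27 h alone 76, 771 and 1190 probes passed. With array weights the count was 2681, against the reference without the unstressed arrays 3255, and without replicate 2 or 3 it was 413 or 571.

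In cold-stressed roots, the chlorophyll-binding antenna protein cab1 fell by 3.73 ± 0.36 and dropped by 3.52 ± 0.33 on its 2 probes (adjusted p = 4.8e-08 and 7.3e-08). CO, the potato CONSTANS gene that links day length to development, rose by 2.53 ± 0.12 (adjusted p = 3.2e-16), with 0.72 ± 0.21 at 3 h, 4.67 ± 0.21 at 9 h and 2.20 ± 0.21 at 27 h. The protein phosphatase StP2C rose by 2.90 ± 0.23, STWRKY8 by 2.61 ± 0.20 and 2.23 ± 0.18, and the cell wall enzyme xth1 by 2.22 ± 0.20. RSI5 fell by 0.63 ± 0.21 at 3 h and rose by 3.16 ± 0.21 at 9 h. The inositol polyphosphate kinase IPMK fell by 3.15 ± 0.43 and isi1 fell by 3.43 ± 0.41 at 3 h, and the vacuolar processing enzyme VPE2 fell by 2.21 ± 0.46 at 3 h.

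Of the 11 photosynthesis probes tested in cold roots 8 fell and 2 rose (adjusted p = 0.018, and 0.52 with an estimated correlation), and 10 of 11 passed when adjusted over the list alone. These genes also mark leaf tissue. PSBO fell by 1.33 ± 0.26 and psbP fell by 1.33 ± 0.22, while the 2 rising probes belonged to PSBR, 2 other probes of which fell. Of 8 carbon fixation probes 6 fell (adjusted p = 0.021), with TK down on both probes, where it fell by 0.95 ± 0.16 and dropped by 0.84 ± 0.12. All 5 cell wall probes rose (adjusted p = 0.0099), protein kinases and phosphatases had 10 of 15 probes that rose and 0 that fell (adjusted p = 0.005), and StWIPK rose by 1.71 ± 0.14. The methionine cycle and polyamines had 12 of 17 probes that rose and 0 that fell (adjusted p = 0.0099), with S-adenosylmethionine decarboxylase (SAMDC) up on 7 of 8 probes, by 0.98 ± 0.09 on one of them. Transcription factors had 7 that rose and 1 that fell of 17 (adjusted p = 0.018). With an estimated correlation the adjusted p of the last 5 lists was 0.52, 0.19, 0.15, 0.52 and 0.12. Of 19 starch and sucrose probes 11 fell and 3 rose (adjusted p = 0.24), with starch phosphorylase glgP at -1.36 ± 0.23 at 9 h. The cyclophilin Cyp rose by 1.47 ± 0.11 on 1 probe and fell on 2 others of 4.

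Cold changed 4143 of 8209 root probes, 2092 up and 2051 down. At 3, 9 and 27 h alone 1164, 2242 and 3335 probes passed, and 213 probes rose at 1 time and fell at another. Without replicate 2 the count was 2323.

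**Figure D2:**
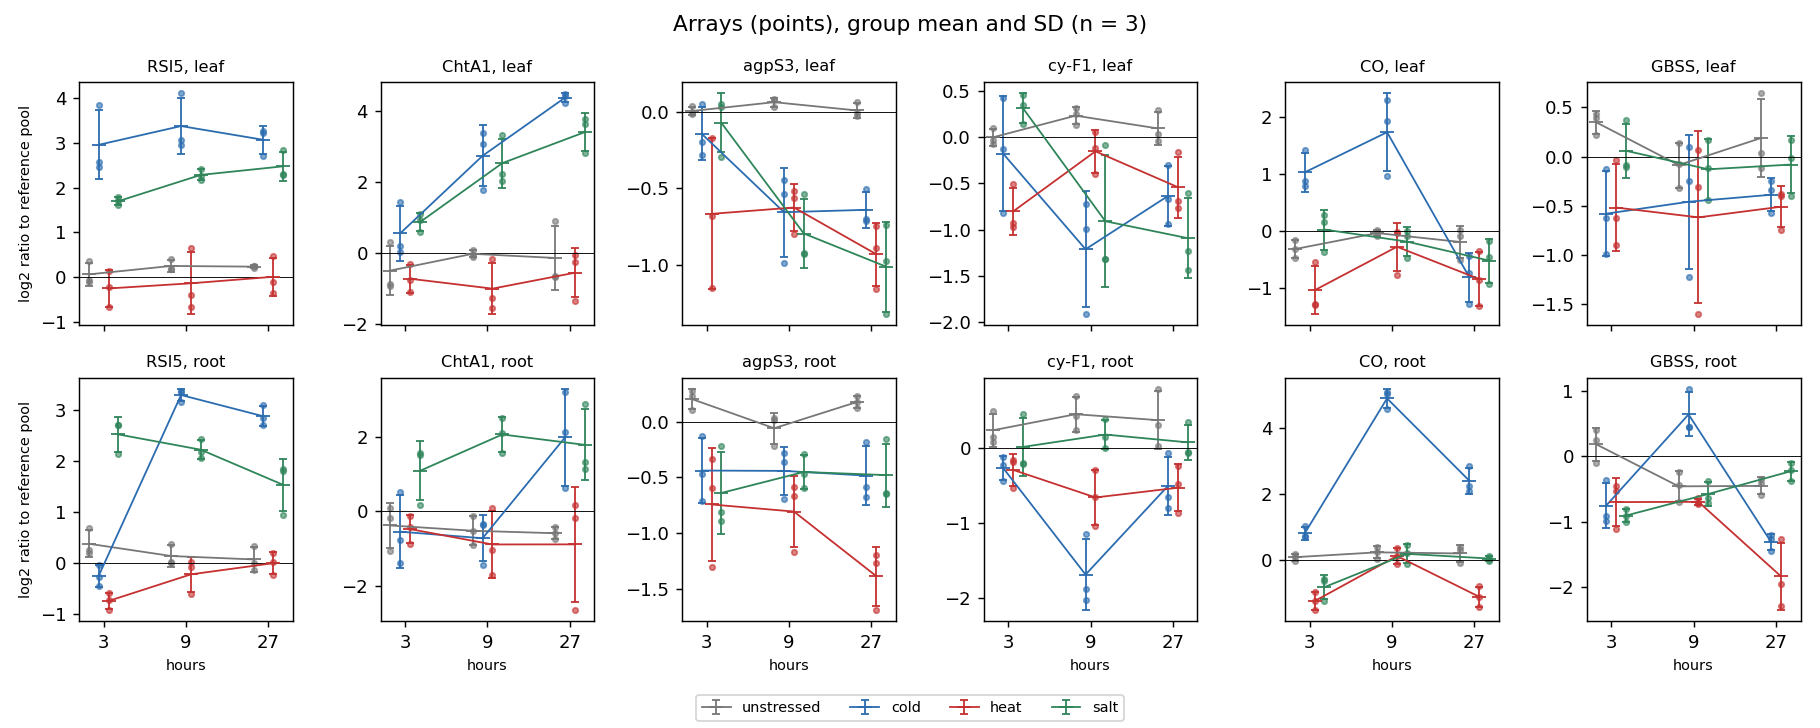
Log2 ratio to the reference pool (vertical axis) of 6 genes at 3, 9 and 27 h (horizontal axis) in leaf and root, with 1 point per array and the mean and SD of each group of 3. CO in cold roots is highest at 9 h, with a change of 4.67, and RSI5 in leaves lies above the unstressed arrays at all 3 times with cold and with salt.

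In heat-stressed roots, VPE2 fell by 2.13 ± 0.24 (the change was -2.13, adjusted p = 7.2e-06) and the glycoalkaloid glycosyltransferase Sgt3 fell by 1.79 ± 0.31 on the probe named by the rule. The leaf marker cab1 fell by 1.77 ± 0.34 and dropped by 1.64 ± 0.36 on its 2 probes, isi1 fell by 1.59 ± 0.24 and IPMK fell by 1.48 ± 0.25, and none of these passed the test of a difference between times (adjusted p = 0.48, 0.45, 0.17 and 0.18). The starch genes agpS3 and GBSS fell by 1.09 ± 0.12 (the change was -1.09) and dropped by 0.84 ± 0.12 (the change was -0.84), and the amylase AMYA1 rose by 0.63 ± 0.12. CO fell by 0.92 ± 0.12 (adjusted p = 2.3e-06), with -1.33 ± 0.21 at 3 h, -0.11 ± 0.21 at 9 h and -1.32 ± 0.21 at 27 h (adjusted p = 0.084 for a difference between times). StSSR1 rose by 0.72 ± 0.11, SI1 by 0.70 ± 0.09 and the translation factor eIF5A5 by 0.68 ± 0.11.

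In the lists, carbon fixation and photorespiration had 5 of 8 probes that fell and 0 that rose (adjusted p = 0.0099), among them GDCST, which fell by 0.91 ± 0.12. Of 11 photosynthesis probes 6 fell (adjusted p = 0.045), also 6 when adjusted over the list alone. With an estimated correlation these adjusted p-values were 0.5 and 0.6. Antioxidant enzymes had 3 of 7 probes that rose and 0 that fell (adjusted p = 0.3), with dehydroascorbate reductase DHAR up by 0.65 ± 0.11 on 1 of 2 probes. The methionine cycle was split, with methionine synthase (MS) down on 3 of 3 probes, where it fell by 0.81 ± 0.14 on one, and acireductone dioxygenase (ARD) up by 0.66 ± 0.10. Of 10 co-chaperone and cyclophilin probes 3 fell and 0 rose, including the DnaJ co-chaperone dnaJ on 1 of 4 probes, which fell by 0.28 ± 0.06.

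Heat changed 2321 of 8209 root probes, 1196 up and 1125 down, and 67 of 174 named genes. At 3, 9 and 27 h alone 672, 532 and 1766 probes passed. Against the reference without the unstressed arrays the count was 4184, and without replicate 1 or 2 it was 995 or 772.

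In salt-stressed roots, ChtA1 rose by 2.14 ± 0.37 and 1.62 ± 0.38 on its 2 probes, RSI5 by 1.90 ± 0.12 (adjusted p = 9.4e-11), HPL by 1.38 ± 0.15 and 1.24 ± 0.12, and CCoAOMT by 1.28 ± 0.15. The protein kinase StMPK4 rose on both probes, by 0.95 ± 0.11 and 0.82 ± 0.11, and the plasma membrane proton ATPase PHA1 by 0.48 ± 0.08. Patatin (pat1), the main storage protein of tubers, fell by 1.24 ± 0.25 and 1.14 ± 0.26 on its 2 probes (the changes were -1.24 and -1.14). At 3 h GBSS fell by 1.09 ± 0.21 and TPT fell by 1.19 ± 0.34 (the change was -1.19), and METK2 rose by 1.45 ± 0.27. Flavonol synthase (FLS) fell by 0.91 ± 0.15 on the probe named by the rule, and 1 of its other probes rose.

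The methionine cycle and polyamines had 8 of 17 probes that rose and 0 that fell (adjusted p = 0.0099, and 0.52 with an estimated correlation). Starch and sucrose genes had 8 of 19 that rose and 2 that fell (adjusted p = 0.093), with AMYA1 up by 0.59 ± 0.12 and glucan, water dikinase (R1) by 0.49 ± 0.08. Wound and oxylipin genes had 4 of 12 that rose and 4 that fell (adjusted p = 0.39), and carbon fixation had 2 of 8 that fell (adjusted p = 0.061). Of the 11 photosynthesis probes 0 passed limma's test in salt roots, 0 when adjusted over the list alone and 2 at unadjusted p below 0.05.

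Salt changed 1921 of 8209 root probes, 1088 up and 833 down, and 66 of 174 named genes. At 3, 9 and 27 h alone 1864, 398 and 215 probes passed. Against the reference without the unstressed arrays the count was 4131, and without replicate 1, 2 or 3 it was 1164, 460 or 1088.

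**Figure D3:**
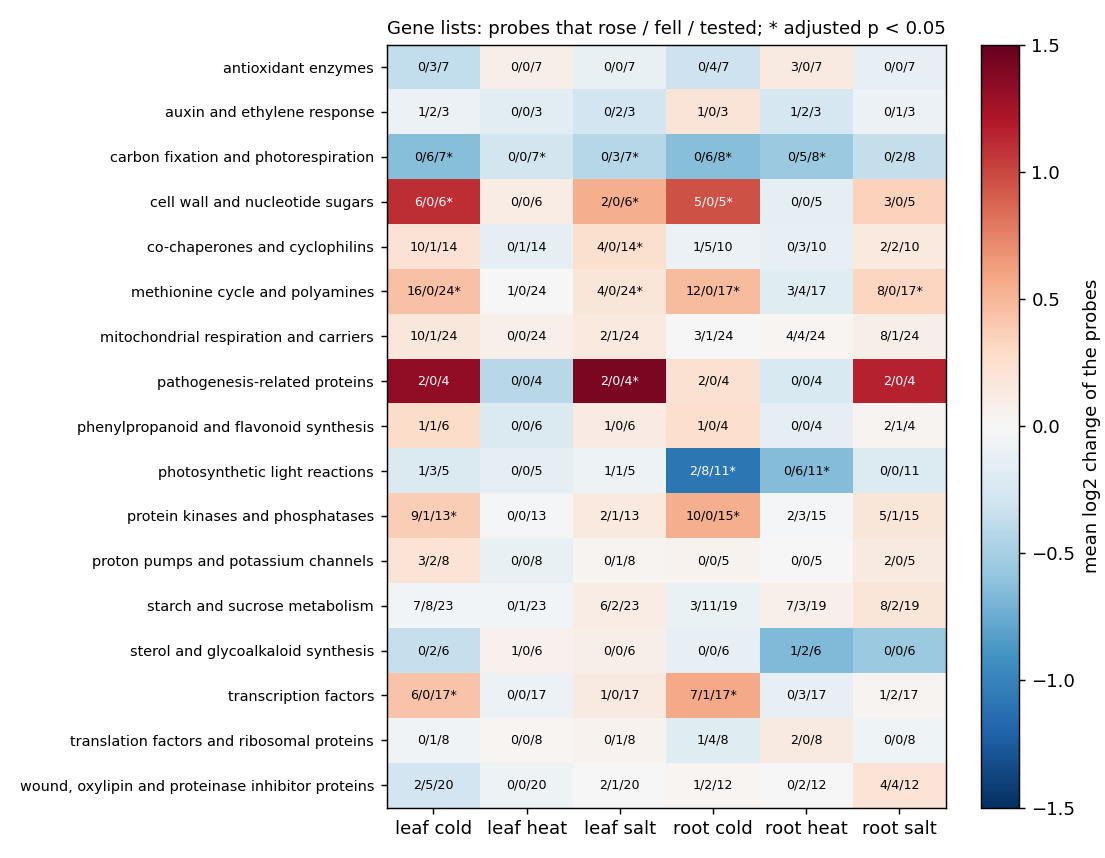
Mean log2 change (colour scale) of 17 gene lists in the 6 comparisons of stress and tissue, with the number of probes that rose, fell and were tested in each cell and an asterisk where camera's adjusted p with the preset correlation was below 0.05. The mean of carbon fixation and photorespiration is below 0 in all 6 comparisons, with an asterisk in 5 of them, which with an estimated correlation had an adjusted p of 0.43, 0.5, 0.43, 0.52 and 0.5. The comparisons of a tissue share their unstressed arrays, so the 6 are not independent.

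Across comparisons, agpS3 fell in all 6, by the means of -0.51 in cold, -0.77 in heat and -0.65 in salt leaves, and -0.56, -1.09 and -0.63 in roots. The comparisons of a tissue share their unstressed arrays, so these 6 are not independent results. GDCST passed the test as lower in 5 comparisons and AMYA1 as higher in 5. RSI5 was higher in 4 comparisons, with cold and salt in both tissues, and lower in 1, heat in roots. ChtA1 and CCoAOMT were higher in 4, and with heat in leaves ChtA1 stood at -0.54 ± 0.27 and CCoAOMT at 0.00, neither past the test. Of the 102 list tests 20 passed with the preset correlation, and 0 with an estimated one, where 10 had an unadjusted p below 0.05. The median, mean and test of a list differed in sign in 11 of the 102, of which 0 passed, among them transcription factors in salt roots and starch genes in heat leaves.

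The comparison of stresses within a tissue asks how far their responses overlap. RSI5, ChtA1, STUGE45, CCoAOMT and SBE1 rose in leaves with both cold and salt, and cy-F1, LPD2, TK and IAA3 fell with both. In leaves 1181 probes changed with both, 536 up and 607 down in both, where independent lists of these sizes would share 145.3 and 143.4, and 38 went opposite ways. The covariance of the mean changes over probes was 0.112, against 0.0074 in simulated unchanged groups with the same unstressed arrays, and the correlation was 0.757 against a simulated 0.503. Leaf cold and heat shared 161 probes, of which 106 went opposite ways, with a covariance of 0.0025 against a simulated 0.0072. Of these 47 were up in cold and 59 down in cold, against 25 and 30.5 for independent lists. Leaf heat and salt shared 79 probes, 30 up and 28 down in both against 13.2 and 10.7, with a covariance of 0.0109 against a simulated 0.0073. In roots cold and salt shared 1237 probes, 499 up and 438 down in both against 277.3 and 208.1 for independent lists, with a covariance of 0.0546 against a simulated 0.0077 and a correlation of 0.32 against a simulated 0.501. Root cold and heat shared 1422, of which 586 went opposite ways, 284 up and 302 down in cold. Independent lists would give 286.7 and 298.8, so this number was near that expected. Root heat and salt shared 679, of which 210 went opposite ways, 73 up and 137 down in heat against 121.4 and 149.1. The covariances of these 2 root pairs were 0.0394 and 0.0387, against simulated values of 0.0078 and 0.0076. Their correlations over probes were 0.216 and 0.321, against 0.5 and 0.493. Those of leaf cold and heat and of leaf heat and salt were 0.027 and 0.155, against 0.503 and 0.504. The simulated groups held no effects, so their correlation near 0.5 came from the shared unstressed arrays alone. It gives no scale for the correlations of the real responses, and a lower value does not mean less alike responses. The simulated groups shared 0 probes, which gives no scale for the shared probes either. Part of the shared probes may come from the shared unstressed arrays, as 3 per time do not give each stress 2 of its own. The difference from the simulated covariance was 0.1044 for cold and salt, -0.0047 for cold and heat and 0.0035 for heat and salt in leaves, with SDs between replicates of 0.019, 0.0306 and 0.0044. In roots it was 0.0469, 0.0316 and 0.0311 in the same order, with SDs of 0.012, 0.0272 and 0.0161. In leaves it turned to 0.0023 for cold and heat without replicate 3 and to -0.0009 for heat and salt without replicate 1, and with scale normalization these were 0.0088 and 0.0119. Without replicate 1 it was 0.0159 for root cold and heat and 0.0195 for root heat and salt, and with scale normalization the former was 0.0502.

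**Figure D4:**
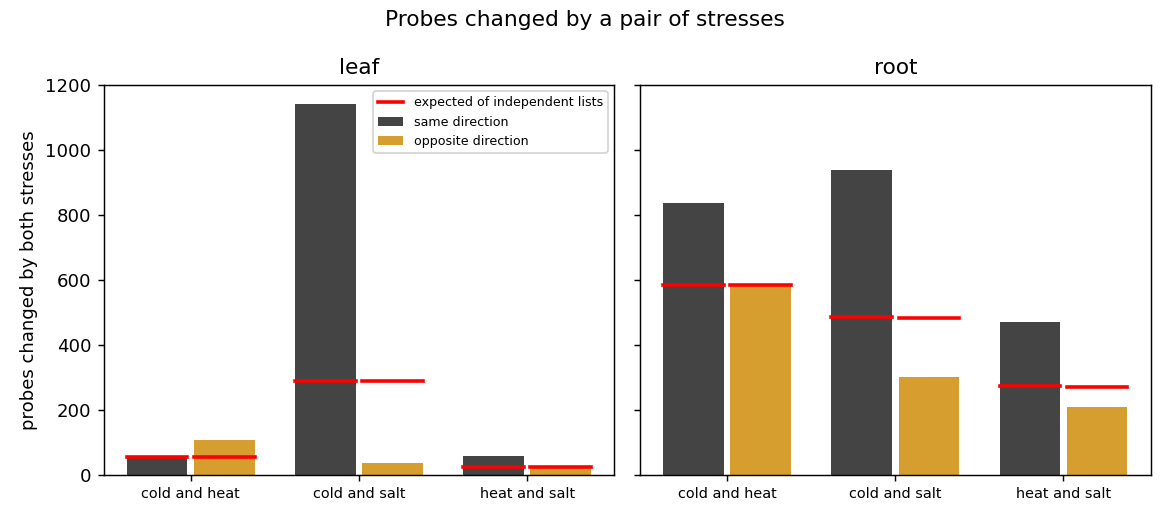
Probes changed by both stresses of a pair (vertical axis), in the same or in opposite directions, for leaf and root, with red lines at the number that independent lists would share. Leaf cold and salt share 536 probes up and 607 down, against 38 in opposite directions.

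Leaf and root responses to the same stress were compared over 7764 probes tested in both. In cold, RSI5, STWRKY8 and StWIPK rose and TK and psbP fell in both tissues, and 2384 probes changed in both against 1732.5 for independent lists, 2075 of them the same way. In heat, agpS3 fell and SI1 and StSSR1 rose in both, and all 269 probes that changed in both went the same way, against 93.1 for independent lists. In salt, RSI5, HPL and CCoAOMT rose in both, and 753 probes changed in both against 366.6, of which 733 went the same way. Across probes, which are not independent replicates, the mean changes of leaf and root correlated at 0.62 in cold, 0.727 in heat and 0.645 in salt. The test of the difference itself called 2107 probes in cold, 34 in heat and 377 in salt. With the reference pool as a block heat gave 92 and salt 733, with scale normalization cold gave 1047 and heat 53, with array weights heat gave 110 and salt 1240, and with a value required on every array heat gave 14. Leaving out 1 replicate gave 845 to 1366 in cold, 0 to 33 in heat and 29 to 125 in salt.

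The response differed between 3, 9 and 27 h for 342 probes in cold leaves, 3 in salt leaves, 2034 in cold roots, 6 in heat roots and 190 in salt roots. Heat in leaves gave 0 probes with limma, and 265 at unadjusted p below 0.05. With the pool as a block the counts were 630 in cold leaves, 35 in salt leaves, 35 in heat roots and 360 in salt roots, with scale normalization 67, 1 and 0 in cold, heat and salt leaves, 1029 in cold roots and 27 in heat roots, and with array weights 1135, 1 and 174 in cold, heat and salt leaves, 51 in heat roots and 488 in salt roots. Leaving out 1 replicate gave 20 to 112 in cold leaves, 0 to 9 in salt leaves, 694 to 1595 in cold roots, 0 to 36 in heat roots and 0 to 30 in salt roots.

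The unstressed samples, which received plain medium, were also set against their reference pools. In leaves 313 of 8726 probes differed from 0, and in roots 1286 of 8209, and the stress effects above were taken against the unstressed samples. A difference between the pools and these samples was not told apart from a dye effect of single probes, as all arrays had the same dye orientation. Leaf and root counts were 1903 and 3506 with scale normalization, 1336 and 2406 with array weights, and 26 to 158 and 151 to 583 with 1 replicate left out.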

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

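Each flagged result was a difference of a stress response between tissues or between times, by limma's test of that difference. Photosynthesis genes in cold-stressed roots, the counts of probes changed by each stress and the gene lists were weighed here as well. The test of photosynthesis genes in cold-stressed roots and the exchanges that kept arrays sharing a pool together were chosen after the result was seen. So was the simulation of a steady change in cold, in place of a planned comparison of the numbers apart at each time that could not test it, and the patterns weighed below had been noticed in the values before they were tested.

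Between leaf and root, the cold response differed for 2107 probes, the heat response for 34 and the salt response for 377. CO rose in cold by 0.83 ± 0.15 in leaf and 2.53 ± 0.15 in root (adjusted p = 2.3e-11). The cyclophilin Cyp on 1 probe stood at 0.19 ± 0.11 in leaf and 1.47 ± 0.11 in root (adjusted p = 2.2e-09). Its other probes disagreed, at 0.09, 0.07 and 0.33 in leaf and -0.55, -0.60 and -0.05 in root. RSI5 stood at 2.96 and 1.78 (adjusted p = 1.2e-08), GP-alpha-1 at 0.57 and -0.15 (adjusted p = 3.3e-06), and the vacuolar processing enzyme VPE2 at 0.93 and -1.23 (adjusted p = 4.9e-06). A 14-3-3 protein stood at 0.86 and 0.30 (adjusted p = 1.1e-05). In heat, the glycoalkaloid glycosyltransferase Sgt3 stood at 0.12 ± 0.24 in leaf and -1.79 ± 0.27 in root (adjusted p = 0.02). In salt, the proton ATPase PHA1 stood at -0.09 in leaf and 0.48 in root (adjusted p = 0.0043), DD at -0.26 and 0.25 (adjusted p = 0.0049), and the uncoupling protein UCP on one probe at 0.21 and -0.34 (adjusted p = 0.014). StMPK4 stood at 0.38 and 0.82 (adjusted p = 0.021), and glucose-6-phosphate isomerase (GPI) on 1 probe at -0.20 and 0.17 (adjusted p = 0.024). NtK-1-like on 1 probe stood at -0.11 and 0.27 (adjusted p = 0.024). Its other probes tested in both tissues stood at 0.08, 0.09 and -0.06 in leaf and 0.20, 0.07 and 0.01 in root.

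Between times, the cold response differed for 342 leaf and 2034 root probes, the salt response for 3 leaf and 190 root probes, and the heat response for 6 root probes. In cold leaves, glucan, water dikinase (R1) stood at 0.31, -0.59 and 1.22 at 3, 9 and 27 h (adjusted p = 0.00069), CO at 1.35, 1.77 and -0.62 (adjusted p = 0.0013), and PEST2 at -0.03, -1.32 and -0.31 (adjusted p = 0.0036). Cysteine synthase CS-B on 1 probe stood at -0.18, -0.85 and -0.09 (adjusted p = 0.0044), and ChtA1 at 1.05, 2.76 and 4.52 (adjusted p = 0.0056). NtK-1-like, on a probe other than that named for salt, stood at 0.03, 0.65 and 0.01 (adjusted p = 0.0088). The mean of this probe over the times was 0.23, and its other probes tested in both tissues had means of 0.23, -0.13 and -0.06. In cold roots, RSI5 stood at -0.63, 3.16 and 2.81 (adjusted p = 2.4e-10), CO at 0.72, 4.67 and 2.20 (adjusted p = 3.5e-10), SAMDC at -0.48, 1.26 and 1.44 (adjusted p = 3.4e-06) and GBSS at -0.94, 1.10 and -0.86 (adjusted p = 6e-06). The factor NAC2 stood at -1.01, 1.38 and 2.47 (adjusted p = 1.2e-05), and Cyp, on its 1 rising probe, at 0.48, 1.42 and 2.50 (adjusted p = 1.6e-05). In salt roots, PPS1 stood at 0.89, -0.43 and -0.61 (adjusted p = 0.01), leucine aminopeptidase (LAP) at -0.73, 0.34 and 0.07 (adjusted p = 0.016), GBSS at -1.09, -0.12 and 0.23 (adjusted p = 0.026), and disproportionating enzyme (dpeP) at -0.17, 0.70 and 0.55 (adjusted p = 0.032).

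In cold, some genes responded at 9 h unlike at 3 h and 27 h, which lie 24 h apart. Of the probes that differed between times 135 in leaf and 406 in root lay apart at 9 h. A sign at 9 h opposite to that at 3 h and 27 h was held by 64 and 203 of these. More lay apart at 3 h, 177 in leaf and 1187 in root, and at 27 h it was 89 and 652. In 100 simulations in which every response only rose or only fell with time, the median number apart at 9 h was 32.5 in leaf and 65 in root, and 14 and 1 simulations gave as many as the real arrays. In leaf, where the highest simulated number was 463, a response changing steadily with the hours of cold was left open. In root, 1 of 100 simulations argues against it for these probes as a set. It was not excluded there, as the highest simulated number, 409, was above the real 406. Unstressed arrays of 9 h that stood apart are argued against for most of these probes in both tissues. Of the 135 leaf and 406 root probes, 125 and 369 were still apart, on the same side, in the stressed ratios alone. The probes had been chosen with the same stressed arrays. These ratios still hold the control reference pools of 9 h, so pools that stood apart at 9 h were not tested. Time of day was not tested either.

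Salt called the most probes at 3 h in root (1864) and at 27 h in leaf (1190). The fit used 1 variance per probe for all times, so a smaller spread between replicates at 1 time could not raise its count above the others. A larger spread could raise it, as the error at that time would be set too low, and this was not tested. The median deviation of arrays from their group mean was 0.1413 at 3 h and 0.09 at 27 h in salt roots, and 0.1183 and 0.109 in salt leaves. The spread was thus larger at the time with most probes in root, and at the time with fewest in leaf. The SD of the change over probes, corrected for measurement error, at 3 h over that at 27 h was 1.64 in root and 0.408 in leaf. This quotient does not test the spread, as each probe's error came from the same shared variance at both times. In the stressed ratios alone the quotient was 0.532 in leaf, which argues against unstressed arrays that stood apart, and 1.38 in root, which left that explanation open there. The control reference pools stayed in these ratios, so pools that stood apart were not tested. A change over time of the salt response differing between leaf and root was left open. Its interaction test called 47 probes, and of 100 exchanges of single leaf and root arrays only the real one gave as many (highest other 40), but of 100 that kept arrays sharing a pool together 7 did (highest other 131).

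Photosynthesis genes, which mark shoot tissue, were lower in cold-stressed roots. A cause that could apply is less shoot tissue in all cold-stressed root samples. The gene cab1 fell by 3.73 ± 0.36, psbP fell by 1.33 ± 0.22 and PSBO fell by 1.33 ± 0.26, while of the PSBR probes 2 rose and 2 fell. Unequal falls do not decide it, since how much of each gene was made in the root itself was not measured. Of these genes 0 had every probe higher, so it cannot be told apart from a change within roots.

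Other splits of the same arrays were drawn to ask whether regrouping the samples gives counts as large. Arrays of the same time and replicate number share a reference pool, so the splits that part every stressed array from the unstressed array of its pool were compared, 64 in all. Only the real one gave as many changed probes for each stress. In leaf these were 3425 for cold (highest other 2271), 285 for heat (95) and 1475 for salt (1266). In root they were 4143 for cold (highest other 3335), 2321 for heat (1419) and 1921 for salt (1312). The other splits drawn, which leave some pool on 1 side, called no more probes than these highest others. Chance is unlikely at 1 of 64, the smallest share that 64 splits can give. It was not excluded, as the shares were not adjusted for the number of tests. For times, whole pools were exchanged within a replicate number, which gives 36 splits. At 1 of 36, the smallest share there, chance is unlikely but not excluded for cold leaves (342, highest other 104) and cold roots (2034, 1047). With single arrays 1 of 100 gave as many for cold leaves (highest other 150) and cold roots (1062). For salt leaves 1 of 36 gave the real 3 (highest other 0), and 2 of 100 with single arrays did. The highest other there, 7, was above the real 3, so chance is unlikely but not excluded. It cannot be excluded for salt roots, where 2 of 36 gave 190 or more and the highest other 193, though with single arrays 1 of 100 did. Nor can it for heat roots, where 6 of 100 splits of single arrays gave 6 or more and the highest other 94, though 1 of 36 did with whole pools. For heat leaves the real count was 0, which every split reaches, so the splits could not test chance there (highest other 1). For the tissue difference in cold chance is likewise unlikely but not excluded. The share was 1 of 64 with whole pools (2107, highest other 1139) and 1 of 100 with single arrays (1971). For heat (34) and salt (377) it was 1 of 64 with whole pools (highest other 6 and 95) and 2 of 100 with single arrays. The highest other of single arrays, 65 and 507, was above the real count, and the shares were not adjusted for the number of tests. For these 2, chance is unlikely but not excluded. For the gene lists it cannot be excluded, as 10 of 100 gave 20 or more and the highest other 29. At single times the 10 splits are too few for a share under 0.05. There the real counts ran from 22 to 3335, and the highest other split gave 9.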

How the results depend on the processing

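The filter on the correlation of the 2 spots of a probe was added after seeing the data. Median centring, robust moderation, the looser missing-value filter and that spot filter left the 17 counts of probes within 1.5 times, and so did the 18-array fits for the 6 stress counts, the only ones they were run for. The looser filter moved the excess covariance of leaf heat and salt from 0.0035 to 0.0022. The cause of the shifts below was not tested, except that leaving out a replicate leaves fewer samples.

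With scale normalization the counts were 1001 for heat in leaf, 1903 and 3506 for unstressed leaf and root, 67, 1, 0, 1029 and 27 for times in leaf cold, leaf heat, leaf salt, root cold and root heat, and 1047 and 53 for tissues in cold and heat. The excess covariance was 0.0767 for leaf cold and salt, 0.0119 for leaf heat and salt, 0.0088 for leaf cold and heat and 0.0502 for root cold and heat. With the pool as a block they were 482 for heat in leaf, 630, 35, 35 and 360 for times in leaf cold, leaf salt, root heat and root salt, and 92 and 733 for tissues in heat and salt. The block changed no other count that it was run for by over 1.5 times, and it was not run for the unstressed samples. With array weights they were 819 and 2681 for heat and salt in leaf, 1336 and 2406 for unstressed leaf and root, 1135, 1, 174, 51 and 488 for times in leaf cold, leaf heat, leaf salt, root heat and root salt, and 110 and 1240 for tissues in heat and salt. With a value required on every array the tissue difference in heat was 14. Against the reference without unstressed arrays, heat gave 1299 in leaf and 4184 in root, and salt 3255 and 4131. There 4 named probes reversed: StSSR1 in root cold (-0.042), SS2 in root heat (-0.055) and dnaJ in root heat (0.024) and root salt (0.16). With an estimated correlation 0 list tests passed. With the sign turned, 0 of the 44 direction cases were positive, which reverses all directions.

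Leaving out each replicate in turn gave 1764 to 2530 for cold, 31 to 63 for heat and 413 to 1234 for salt in leaf, and 2323 to 3581, 772 to 1760 and 460 to 1164 in root. Unstressed samples gave 26 to 158 in leaf and 151 to 583 in root. Times gave 20 to 112 in leaf cold, 0 to 9 in leaf salt, 694 to 1595 in root cold, 0 to 36 in root heat and 0 to 30 in root salt. Tissues gave 845 to 1366 in cold, 0 to 33 in heat and 29 to 125 in salt, and the excess covariance was -0.0009 to 0.0034 for leaf heat and salt, -0.0225 to 0.0023 for leaf cold and heat, 0.0159 to 0.0436 for root cold and heat and 0.0195 to 0.04 for root heat and salt. The lowest came without replicate 2, except for leaf heat (replicate 3), times in leaf salt (0 without replicate 2 or 3), tissues in heat and those covariances (replicate 1). Of named results 69 lost their call without replicate 2, 35 without replicate 1 and 50 without replicate 3. The number of arrays limits precision, and signal over background was not available.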
